A study of Mus musculus with 6 samples.

How the data were processed

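The labels describe small RNA sequencing of GC-1spg cells, with 3 libraries after METTL3 siRNA and 3 after control siRNA, collected at 48 h. Per the submitters' processing notes, fastp, Bowtie2, StringTie and RSEM were used with the mouse build mm10, with no role or version stated. How the authors named and predicted miRNAs, and which test gave their p-values, is not given in the sources used here.

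The authors deposited a table of all miRNAs and a table of differently expressed miRNAs. Per the file headers, the first value per library in the deposited tables is a count of reads per mature miRNA name, in whole numbers. The other deposited value per library is a TPM, and each TPM equals its count scaled by one library total (CPM), with 0 written as 0.01. The largest gap between a deposited TPM and its count over that total was 5e-05. The authors' group means are means of the 3 TPM values of a group, and the authors' log2 fold change is the log2 ratio of the si-METTL3 mean over the si-NC mean. The authors' p-value and FDR stand beside it, and the deposited length and total are the number of bases of the sequence and the sum of its 6 counts. Of the table of all miRNAs, 2 lines were emptied before the data were handed over, and they are not analysed here. The table then held 1224 names, 679 of them mouse names (94.6% of the counts), 478 names of other species (5.36%) and 67 predicted names (0.0276%). It held 91.4% to 92.1% of the totals behind the TPM, which were taken as library sizes. At these depths 3 counts in a library stand for 0.489 to 0.75 CPM. Different names with one sequence, 60 in all, were kept apart.

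Counts were tested with edgeR's quasi-likelihood test, two-sided, after TMM scaling and filterByExpr, with robust dispersion estimates, no block and the Benjamini-Hochberg adjustment at 0.05. The design leaves 4 residual degrees of freedom and the common coefficient of biological variation was 0.0583. Values are CPM with TMM scaling unless shares or library totals are named, while sums of invertebrate names and ratios of few counts are over library totals, and log2 folds are si-METTL3 over si-NC with their standard errors (SE). Lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the 18 lists with at least 3 tested members. Measures of composition were compared with exact two-sided permutation tests, adjusted over 31 measures. Ratios of a longer variant to its mouse form were tested with limma on log2 ratios for 79 pairs with a mean of at least 50 counts. Correlations are across miRNAs, which are not independent replicates. Ratios of few counts have exact binomial intervals at 95%, and a group at 0 was given a floor of 3 counts over the group. Intervals and floors cover counting error only.

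The tests of the counts, of the lists, of the overlap with the authors' list and of composition, the lists, the rule for named miRNAs and the alternatives named below as fixed beforehand were set before the data were examined. The test of variant ratios, the comparison of invertebrate names, the correlations across miRNAs and the motif test were added after the data were seen. The rule takes the 8 most abundant names, the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 10 CPM and no overlap between groups, up to 4 members per list, and, among mouse names, the 5 rises and 5 falls of largest fold on the authors' list. Names outside it are said to have been chosen after their values were seen. The 23 lists were the let-7 family, the miR-17-92 clusters, undifferentiated spermatogonia, the miR-34/miR-449 family, the miR-290-295 and miR-302/miR-367 clusters, the X-linked testis cluster, the miR-322/miR-503 cluster, the Dlk1-Dio3 cluster, the Sfmbt2 cluster, the miR-15/16, miR-29 and miR-30 families, the miR-200 and miR-183 clusters, p53-responsive miRNAs, NF-kB and interferon miRNAs, miRNAs linked to METTL3 in other cells, Drosha-independent miRNAs, and miRNAs of blood cells, muscle, neurons, endothelium, liver and serum, and testis somatic cells. The list of 16 invertebrate names was written from general knowledge after the names in the table were seen. The makeup of these names was compared over 5 libraries by a chi-square over degrees of freedom, set against 10000 draws of mouse names of like counts, so that spread beyond counting error is covered.

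The alternatives fixed beforehand were a replicate block, leaving out each library, DESeq2 size factors, library totals alone, no filter, a filter of 10 CPM in 3 libraries, mouse names only, limma on log2(TPM + 1), log2(TPM + 0.5) and log2(TPM + 5), DESeq2's Wald test, edgeR's exact test, the most abundant arm of each hairpin, an estimated correlation, and for composition the 20 most abundant names. Those chosen after seeing the data were library sizes summed over the table, variants summed per mouse arm, names on a mouse hairpin only, a GC trend removed per library, thinning to one depth, and a term for the 3 sets of libraries that share foreign miRNA names. Sequences were matched to hairpins in GENCODE M21 transcripts on GRCm38 (mm10), allowing for last or first bases that the hairpin does not hold; of the names of other species, 356 matched a mouse hairpin in this way and 331 could be assigned to an annotated mouse arm.

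The main test was tested on simulated data of the same size and spread, in 5 runs of 622 names with 200 changed. It recovered 33.4% of names changed by a log2 fold of 0.25, 59.1% at 0.5 and 86.4% at 1. Of the calls 3.09% were wrong and 0.9% of unchanged names were called. In separate runs only 12 names were changed, by a log2 fold of 0.5. A list of these 12 had a camera p under 0.05 in 100% of runs and a random list of 12 in 0%. That p was not adjusted over lists. The runs therefore do not show how the adjusted list test acts on lists of related miRNAs. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.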

Results

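Small RNA was sequenced from GC-1spg cells, an immortalised mouse line derived from the testis that is used as a model of spermatogonia, the germ cells that found spermatogenesis. The cells had received an siRNA against METTL3 (si-METTL3) or a control siRNA (si-NC) and were collected after 48 h. METTL3 is the catalytic subunit of the complex that writes N6-methyladenosine (m6A) into RNA, and in other cells it has been linked to the processing of primary miRNA transcripts. The series asks how small RNA differs between spermatogonia that differ in m6A, and the one comparison its labels imply is 3 si-METTL3 libraries against 3 si-NC libraries. The totals behind the deposited normalised values were 4052812, 3998058 and 4003537 reads in si-NC 1 to 3, and 6132668, 4473804 and 4567548 in si-METTL3 1 to 3. Between 1047 and 1126 miRNA names were detected per library. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values given here measure the spread between these libraries, which may be technical.

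The labels print one and the same 19-base sequence, GCTACCGTATGGGACATTA, for the METTL3 siRNA and for the control siRNA. In GENCODE M21, on the genome build GRCm38 (mm10), this sequence lay in 6 of 15 annotated Mettl3 transcripts and in no transcript of another gene. Its position is chromosome 14, 52297548 to 52297566, minus strand, in the coding part of exon 6 of Mettl3-201. Counts of mature miRNAs carry no measurement of Mettl3 mRNA, so the knockdown itself could not be checked in these libraries, and the groups are those given by the sample titles.

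A few miRNAs made up most of each library. Mouse names are given here without their prefix, and names of other species carry the endings -x, -y or -z, whose meaning is not given in the sources used here. In si-NC the 10 most abundant names held 58.5% ± 0.509 (SD, n = 3) of a library. The first was miR-21a-5p (chromosome 11, 86584120 to 86584141, minus strand, in an exon of Vmp1), widely known for its abundance in dividing cells, at 140456 ± 3092 CPM (counts scaled to a library of equal size by TMM) in si-NC (mean ± SD, n = 3) and 141262 ± 8146 in si-METTL3. The other names among the 8 most abundant were miR-27b-3p, miR-99b-5p, miR-125b-5p, miR-99a-5p, miR-24-3p, miR-30a-5p and miR-21-x, the last a 24-base sequence that carries the name of another species and matches the miR-21a-5p arm except for its last bases. No miRNA of the miR-290-295 or miR-302/miR-367 clusters, which mark pluripotent cells, was listed in the table.

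After METTL3 siRNA many miRNAs shifted by small amounts in both directions, relative to the rest of the library. The scaling brings the libraries to one level (median log2 fold of all tested names 0.0054). A rise or loss shared by all miRNAs would therefore not show here. Of 622 names tested, 182 (29.3%) passed an adjusted p of 0.05 (edgeR's quasi-likelihood test, two-sided, Benjamini-Hochberg adjustment), 110 higher and 72 lower in si-METTL3. The median fold was 1.37 among the higher and 0.785 among the lower names. Only 7 of the 182 changed by at least 1 on the log2 scale, 56 by 0.5 to 1, 74 by 0.25 to 0.5 and 45 by under 0.25. Of the 182, 129 were mouse names (74 higher, 55 lower), 51 carried a name from another species and 2 were predicted. In 256 names (41.2%) all si-METTL3 libraries lay on one side of all si-NC libraries, where chance gives 10%. That held for 176 of the 182. Without each of the 6 libraries in turn, 124 of the 182 stayed past the threshold in every refit. The split between directions depended on the scaling. It was 60.4% higher here, 44.9% (83 higher, 102 lower) with library totals alone, 44.9% to 45.3% with limma on the deposited TPM and 46.5% (94 higher, 108 lower) after a GC trend was removed.

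**Figure D1:**
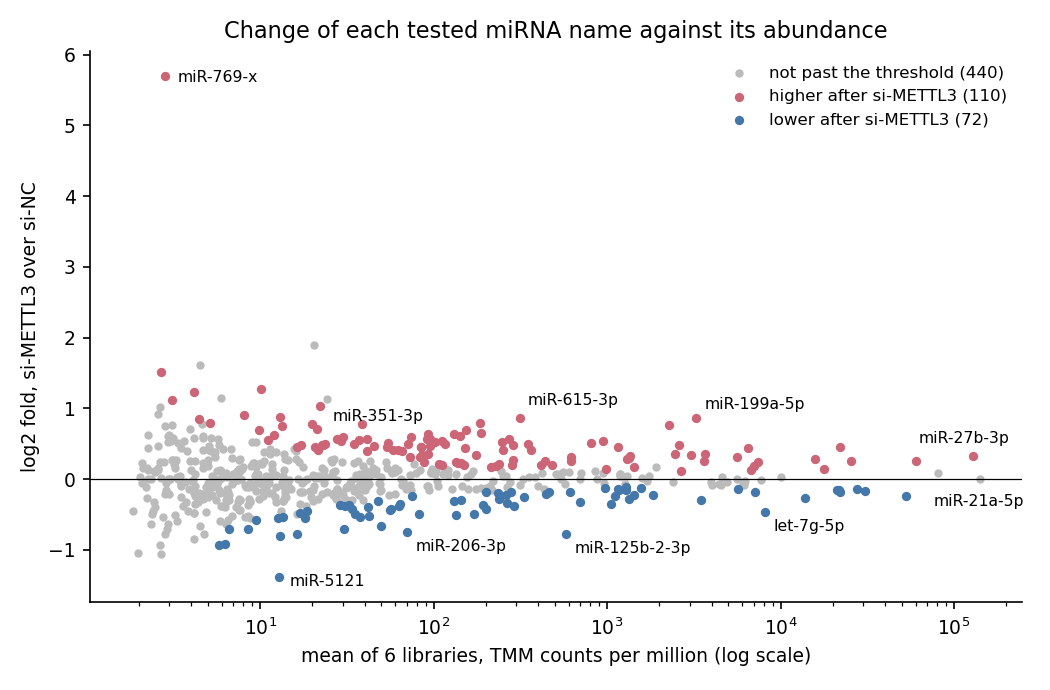
Log2 fold of si-METTL3 over si-NC (y axis) against the mean of the 6 libraries in TMM-scaled CPM (x axis, log scale) for the 622 names tested, with the 110 higher names in red, the 72 lower names in blue and the 440 others in grey. Most coloured points lie within 1 of 0 on the log2 scale, and miR-769-x, at 1 count summed over si-NC and 84 over si-METTL3, stands alone at the top.

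Among the most abundant miRNAs, miR-27b-3p, a regulator of lipid metabolism and angiogenesis genes in other tissues, rose 1.26-fold (log2 fold 0.33 ± 0.04 SE, adjusted p 7.1e-07, edgeR), from 113717 ± 2446 to 142737 ± 5027 CPM (SD, n = 3). Its mature sequence lies on chromosome 13, 63300760 to 63300780, plus strand, in an exon of 2010111I01Rik. miR-125b-5p, the lin-4 homologue, rose 1.20-fold (log2 fold 0.26 ± 0.04, adjusted p 1.9e-05), and miR-21-x rose by a log2 fold of 0.26 ± 0.04 (adjusted p 1.2e-05). miR-99a-5p fell by 0.24 ± 0.04 (adjusted p 7.5e-05), miR-24-3p fell by 0.17 ± 0.04 (adjusted p 0.0014) and miR-30a-5p fell by 0.14 ± 0.04 (adjusted p 0.0074) on the log2 scale. miR-21a-5p (log2 fold 0.0082 ± 0.04, adjusted p 0.922) and miR-99b-5p (0.09 ± 0.04, adjusted p 0.144) did not pass.

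The clearest rise was that of miR-199a-5p, a miRNA of mesenchymal cells that is made with miR-214 from the Dnm3os transcript. It went from 2316 ± 7.71 to 4227 ± 134 CPM (SD, n = 3), a log2 fold of 0.87 ± 0.04 (SE, adjusted p 6.5e-14, edgeR). Its sequence lies at 2 loci, chromosome 1, 162217844 to 162217866, plus strand, in an exon of Dnm3os, and chromosome 9, 21496537 to 21496559, minus strand, antisense to an intron of Dnm2. miR-214-5p (log2 fold 0.04, adjusted p 0.914, edgeR) and miR-214-3p (0.15, adjusted p 0.161), named after their values were seen, did not pass. miR-615-3p, from an intron of Hoxc5 (chromosome 15, 103014969 to 103014990, plus strand), rose from 222 ± 11.7 to 404 ± 17 CPM, a log2 fold of 0.87 ± 0.06 (adjusted p 4.7e-11). The other names in the rule's 10 largest rises were miR-12135-z (log2 fold 1.28 ± 0.24), miR-351-3p (1.03 ± 0.16), miR-700-y (0.88 ± 0.19), miR-872-3p (0.79 ± 0.07), miR-185-x (0.78 ± 0.12), miR-342-y (0.78 ± 0.17), miR-23-z (0.77 ± 0.05) and miR-210-5p (0.75 ± 0.18), with adjusted p between 5.1e-12 and 0.0026. miR-210 is known as a hypoxia-induced miRNA. miR-700-y, miR-185-x, miR-342-y and miR-23-z match mouse hairpins except for their last bases, and miR-12135-z, an 18-base sequence, matched no annotated mouse transcript.

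The largest fall was that of miR-5121, from 18.7 ± 3.64 to 7.07 ± 1.38 CPM (SD, n = 3), a log2 fold of -1.39 ± 0.20 (SE, adjusted p 1.1e-05, edgeR). Its sequence lies on chromosome 7, 45126925 to 45126945, minus strand, in an annotated exon of the ribosomal protein gene Rpl13a on the same strand. Fragments of other RNA from that locus would carry the same name. miR-125b-2-3p, the less abundant arm of a hairpin whose other arm gives miR-125b-5p, fell from 733 ± 38.9 to 427 ± 18.1 CPM (log2 fold -0.78 ± 0.05, adjusted p 4.7e-11). miR-206-3p, a muscle miRNA, fell from 88.6 ± 2.06 to 52.2 ± 6.93 (log2 fold -0.75 ± 0.09, adjusted p 7.5e-07). The other falls were those of miR-29b-1-5p (log2 fold -0.80 ± 0.20), miR-326-3p (-0.77 ± 0.17), miR-200a-3p (-0.71 ± 0.15), miR-30-y (-0.67 ± 0.10), miR-743b-3p (-0.55 ± 0.18), miR-1839-3p (-0.54 ± 0.18) and miR-193a-3p (-0.54 ± 0.11), with adjusted p between 1.3e-05 and 0.027. The call of miR-743b-3p was lost when any 1 library other than si-NC 3 was left out (adjusted p 0.054 to 0.140), and that of miR-1839-3p without si-NC 3 or si-METTL3 2 (0.074 and 0.159). The libraries fell into 3 sets by the invertebrate miRNA names they held, si-NC 1 alone, si-METTL3 1 with si-NC 2 and si-NC 3, and si-METTL3 2 with si-METTL3 3. A term for these sets was an alternative chosen after seeing the data. Only the set of si-METTL3 1, si-NC 2 and si-NC 3 holds both groups. With the term the log2 fold therefore comes from si-METTL3 1 against si-NC 2 and si-NC 3 alone. The calls of miR-12135-z (log2 fold 0.75 ± 0.29), miR-210-5p (0.49 ± 0.27), miR-29b-1-5p (-0.69 ± 0.27), miR-743b-3p (-0.50 ± 0.27), miR-1839-3p (-0.34 ± 0.24) and miR-193a-3p (-0.45 ± 0.18) did not hold in that fit, each with a larger SE than without the term.

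**Figure D2:**
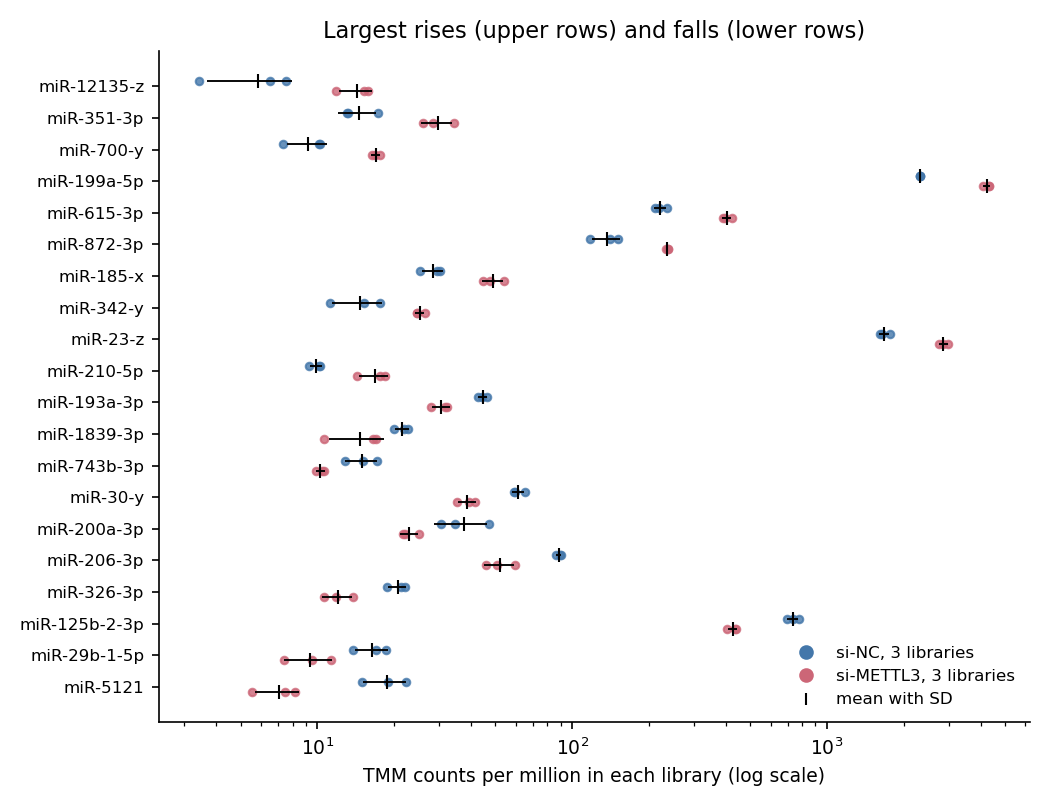
TMM-scaled CPM (x axis, log scale) in each of the 3 si-NC (blue) and 3 si-METTL3 (red) libraries for the 10 largest rises (upper part) and the 10 largest falls (lower part), with each group's mean as a black tick and its SD as a bar. For each miRNA shown the 3 points of one group lie wholly to one side of the 3 points of the other, as the rule for this selection requires.

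Of the 23 lists of miRNAs fixed beforehand, 18 had at least 3 tested members. None of the 18 passed camera's competitive test (two-sided, preset correlation 0.01, Benjamini-Hochberg adjustment over the lists), where 3 had an unadjusted p under 0.05. With an estimated correlation none passed and 1 had an unadjusted p under 0.05. Camera on log2 values of the deposited TPM, as used with limma, passed 1 list. For DESeq2's Wald test and edgeR's exact test camera ran on the same log2 values as in the main test. Their 0 lists repeat that result and are no separate evidence. Unless said otherwise, the counts given per list from edgeR's test were the same over all names and adjusted over the list alone.

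The group nearest to the threshold was the miR-322/miR-503 cluster, an X-linked polycistron whose miRNAs repress cyclins and other cell cycle genes. Of its 12 measured members, 8 rose and none fell, and the list's median log2 fold was 0.41 (camera p 0.0030, adjusted p 0.054, with an estimated correlation p 0.035 and adjusted p 0.631). miR-322-3p rose from 667 ± 30.9 to 949 ± 29.9 CPM (SD, n = 3), a log2 fold of 0.51 ± 0.05 (SE, adjusted p 1.7e-08, edgeR). The other arm, miR-322-5p, named here after its values were seen, did not rise (log2 fold -0.03 ± 0.07, adjusted p 0.827). miR-503-5p rose by a log2 fold of 0.64 ± 0.07 (adjusted p 3.7e-07), miR-351-5p by 0.33 ± 0.05 (adjusted p 3.1e-06) and miR-351-3p by 1.03 ± 0.16 (adjusted p 1.9e-05). miR-351-3p lies on chromosome X, 53053276 to 53053296, minus strand, and miR-322-3p on chromosome X, 53054269 to 53054289, minus strand, both outside annotated genes. With the term for the 3 sets of libraries, so from si-METTL3 1 against si-NC 2 and si-NC 3 alone, the median was 0.26. The list passed in 11 of 25 alternatives, with camera adjusted p from 0.0091 to 0.631. Of the 11, 3 were refits without 1 library (without si-NC 1, adjusted p 0.046, without si-NC 2, 0.037, and without si-METTL3 1, 0.0498). Of the 25, the settings of DESeq2's Wald test and edgeR's exact test repeat the main camera test.

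The related miR-15/16 family, which shares the seed of miR-322-5p and miR-497a-5p, had 5 members higher and 1 lower of 12 (camera adjusted p 0.292). miR-15b-5p rose by a log2 fold of 0.29 ± 0.04 (adjusted p 1.2e-05, edgeR) and miR-322-3p, also counted here, by 0.51. The arm with the seed, miR-322-5p, did not rise (log2 fold -0.03 ± 0.07, adjusted p 0.827). The most abundant member, miR-16-5p, had a log2 fold of -0.09 ± 0.04 (adjusted p 0.124), and miR-15a-3p 0.57 ± 0.28 (adjusted p 0.141). In the miR-34/miR-449 family, p53-responsive miRNAs that are also abundant in meiotic male germ cells, 3 of 5 members rose and none fell (camera adjusted p 0.308). These were miR-34c-5p (log2 fold 0.25 ± 0.05, adjusted p 5.1e-04, edgeR), miR-34c-3p (0.63 ± 0.18, adjusted p 0.0095) and miR-34b-3p (0.46 ± 0.15, adjusted p 0.025). The call of miR-34b-3p was lost with library totals alone (adjusted p 0.059) and without si-NC 2, si-NC 3, si-METTL3 1 or si-METTL3 2 (0.067 to 0.097).

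The let-7 family, which restrains proliferation and rises with differentiation, had 2 members higher and 4 lower of 20 (camera adjusted p 0.501). let-7g-5p, named here after its values were seen, fell by 0.46 ± 0.05 on the log2 scale (adjusted p 4.3e-08, edgeR), and let-7a-5p, likewise, fell by 0.26 ± 0.05 (adjusted p 3.2e-04). The most abundant members, let-7f-5p and let-7c-5p, fell by 0.15 ± 0.05 (adjusted p 0.012) and 0.16 ± 0.05 (adjusted p 0.010). The first call was lost without si-NC 2 (log2 fold -0.12, adjusted p 0.082) and the other without si-METTL3 2 (log2 fold -0.10, adjusted p 0.097). miR-98-3p (log2 fold 0.77 ± 0.32, adjusted p 0.073) and let-7c-1-3p (-0.63 ± 0.27, adjusted p 0.082) did not pass. The summed share of the family was 9.60% ± 0.331 of a library in si-NC and 8.24% ± 0.413 in si-METTL3 (SD, n = 3, exact two-sided permutation p 0.1, the smallest that 3 against 3 libraries can give, adjusted p 0.155). The miR-17-92 cluster and its paralogues, drivers of proliferation, had 1 member higher and 4 lower of 17 (camera adjusted p 0.508). miR-93-3p rose by a log2 fold of 0.55 ± 0.13 (adjusted p 0.0024, edgeR). miR-92a-3p fell by 0.14 ± 0.04 (adjusted p 0.011), a call lost without si-NC 1 or si-METTL3 2 (adjusted p 0.056 in both). miR-25-3p (log2 fold -0.07 ± 0.04, adjusted p 0.201) and miR-20a-3p (-0.21 ± 0.10, adjusted p 0.124) did not pass.

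Among miRNAs known from undifferentiated spermatogonia, 4 of 18 measured members rose and 4 fell (camera adjusted p 0.785). The list's median (0.0032) and mean (-0.00093) differ in sign. The falls were both arms of miR-221 and of miR-222, which keep spermatogonia undifferentiated in the mouse. miR-222-5p fell by 0.50 ± 0.12 on the log2 scale (adjusted p 0.0024, edgeR), and miR-221-3p and miR-222-3p, named after their values were seen, fell by 0.24 ± 0.04 (adjusted p 8.0e-05) and 0.28 ± 0.05 (adjusted p 3.5e-05). miR-322-3p was among the rises. The abundant miR-21a-5p and miR-10b-5p (log2 fold 0.03 ± 0.04, adjusted p 0.625) did not pass. The X-linked testis cluster, which is expressed in male germ cells, had 2 members lower and none higher of 13 (camera p 0.036, adjusted p 0.235). These were miR-743b-3p and miR-741-3p (log2 fold -0.38 ± 0.10, adjusted p 0.0045, edgeR), while miR-871-3p (-0.16 ± 0.14, adjusted p 0.445) and miR-547-3p (-1.05 ± 0.40, adjusted p 0.053) did not pass. Without si-NC 1 this list passed (adjusted p 0.046, range over 25 alternatives 0.046 to 0.738). The list of the cluster in an intron of Sfmbt2, set by name, had 22 measured members, 21 of them with a hairpin in that gene. Some members hold identical values under different names, such as miR-466a-3p and miR-466b-3p, named after their values were seen. The same holds for miR-465a-3p and miR-465b-3p, likewise, in the X-linked list. Camera counted such copies as separate members, which a preset correlation of 0.01 does not allow for. Of the 22, 0 passed in edgeR's quasi-likelihood test, where 1 had an unadjusted p under 0.05, and 0 in DESeq2, edgeR's exact test and limma (camera adjusted p 0.241, and 0.046 without si-NC 1, the lowest of 25 alternatives, which reached up to 0.738). The 1 with an unadjusted p under 0.05 was miR-466i-3p (log2 fold -0.66 ± 0.30, adjusted p 0.114), whose only annotated locus is on chromosome 13, 17747552 to 17747573, plus strand, antisense to an intron of Cdk13. The members miR-467a-5p (log2 fold 0.10 ± 0.09, adjusted p 0.427), miR-467b-5p (0.10 ± 0.09, 0.434) and miR-467a-3p (-0.48 ± 0.32, 0.287) come from repeated hairpins whose reads cannot be assigned to one copy. In the Dlk1-Dio3 cluster only miR-127-3p could be tested (log2 fold -1.05 ± 0.44, adjusted p 0.081 over all names), and it passed when adjusted over the list alone, which held that 1 member.

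Of the miRNAs linked to METTL3 in other cells, 1 of 14 measured members rose and 5 fell (camera adjusted p 0.292). The falls were both arms of miR-221 and of miR-222, and miR-143-3p (log2 fold -0.23 ± 0.04, adjusted p 2.2e-04, edgeR), and the rise was that of miR-93-3p. The abundant members miR-25-3p and let-7e-5p (log2 fold 0.0053 ± 0.04, adjusted p 0.949) did not pass. Of miRNAs that bypass Drosha, the nuclear enzyme that frees hairpins from primary transcripts, 1 of 7 rose and 1 fell (camera adjusted p 0.785). miR-484 rose by a log2 fold of 0.36 ± 0.04 (adjusted p 4.3e-07, edgeR), and miR-320-3p had -0.15 ± 0.07 (adjusted p 0.101). miR-877-3p fell by 0.46 ± 0.16 (adjusted p 0.038), a call lost without si-NC 1, si-NC 3, si-METTL3 1 or si-METTL3 2 (adjusted p 0.081 to 0.112).

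The miR-30 family had 2 members higher and 3 lower of 11 (camera adjusted p 0.626), with miR-30e-5p higher (log2 fold 0.25 ± 0.04, adjusted p 2.5e-05, edgeR) and miR-30c-2-3p (-0.37 ± 0.06, adjusted p 9.3e-05) and miR-30b-3p (-0.31 ± 0.10, adjusted p 0.018) lower. The call of miR-30b-3p was lost when any 1 library other than si-NC 1 or si-METTL3 1 was left out (adjusted p 0.050 to 0.064). The miR-29 family, repressors of collagen genes, had 1 member lower of 6, miR-29b-1-5p (camera adjusted p 0.510). Its abundant members miR-29a-3p (log2 fold -0.07 ± 0.04, adjusted p 0.163) and miR-29b-3p (0.04 ± 0.06, adjusted p 0.625) did not pass, nor did miR-29b-2-5p (0.24 ± 0.39, adjusted p 0.701). The joint list of the epithelial miR-200 and the miR-183 clusters had 2 members higher and 3 lower of 10 (camera adjusted p 0.406). The miR-200 side held the falls, with miR-200a-3p and, named after their values were seen, miR-141-3p (log2 fold -0.52 ± 0.11, adjusted p 7.1e-04, edgeR) and miR-200b-3p (-0.58 ± 0.22, adjusted p 0.048, lost without si-NC 1, si-NC 3, si-METTL3 1 or si-METTL3 3 at 0.105 to 0.224). The miR-183 side held the rises, both arms of miR-182, with miR-182-5p at a log2 fold of 0.18 ± 0.04 (adjusted p 6.9e-04). miR-183-5p (-0.0080 ± 0.04, adjusted p 0.914) and miR-96-3p (-0.93 ± 0.42, adjusted p 0.106) did not pass.

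The p53-responsive list had 3 members higher and 3 lower of 12 (camera adjusted p 0.785). Its median (-0.06) and its mean (0.03) differ in sign, and camera's direction was down. The rises were those of the miR-34 family, and the falls were miR-143-3p, miR-192-5p (log2 fold -0.13 ± 0.05, adjusted p 0.047, edgeR) and, named after its values were seen, miR-107-3p (-0.28 ± 0.06, adjusted p 5.4e-04). The call of miR-192-5p was lost when any 1 library other than si-NC 2 was left out (adjusted p 0.055 to 0.230). Among miRNAs of NF-kB and interferon signalling, 2 of 11 rose and 1 fell over all names, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p 0.838). miR-146b-5p rose by a log2 fold of 0.48 ± 0.04 (adjusted p 4.6e-09, edgeR), and miR-155-5p, named after its values were seen, fell by 0.26 ± 0.05 (adjusted p 6.1e-04). miR-132-3p (-0.50 ± 0.20, adjusted p 0.059) and miR-21a-3p (-0.05 ± 0.04, adjusted p 0.489) did not pass over all names.

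**Figure D3:**
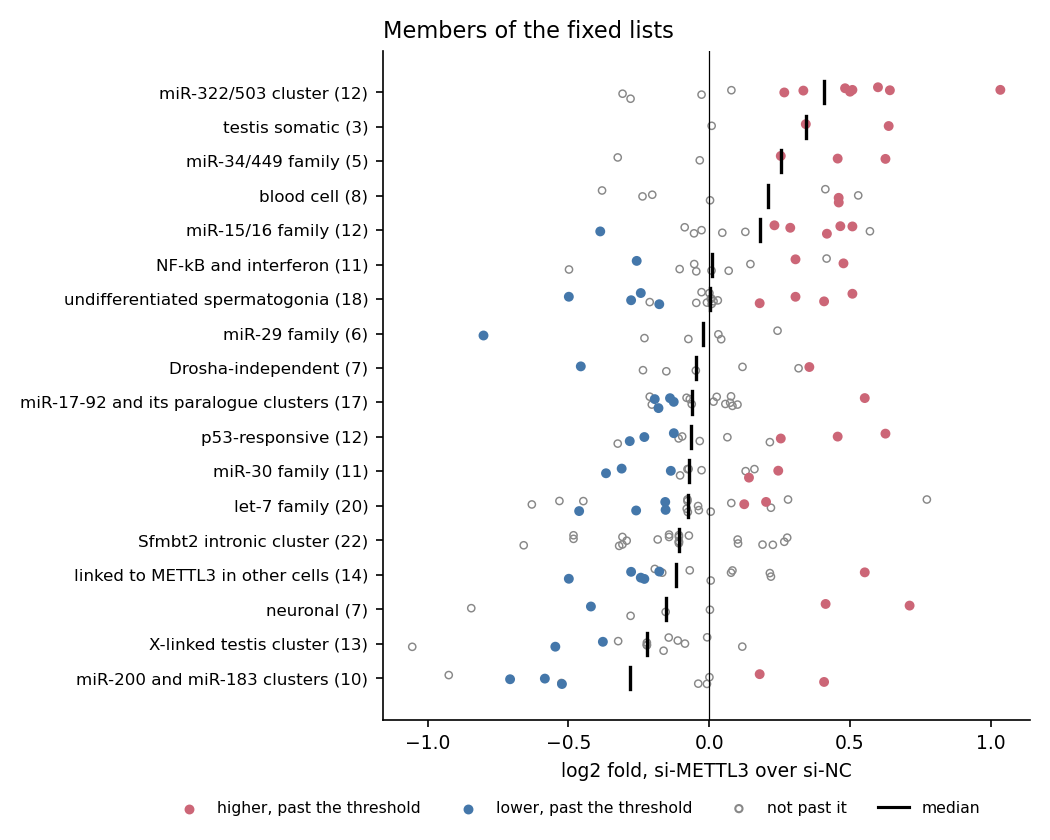
Log2 fold of si-METTL3 over si-NC (x axis) for each measured member of the 18 lists that had at least 3 tested members (y axis, number of members in brackets), with filled red and blue points for members higher or lower past an adjusted p of 0.05, open points for the others and a black bar for the list's median. The miR-322/miR-503 cluster has the highest median, 0.41, with 8 filled points to the right of 0 and none to the left.

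Lists of miRNAs typical of other cell types described what else the cultures could hold, and none of those tested passed. Among testis somatic miRNAs 2 of 3 rose (camera p 0.039, adjusted p 0.235), both arms of miR-140. miR-140-3p rose by a log2 fold of 0.34 ± 0.04 (adjusted p 4.3e-07, edgeR) and miR-140-5p by 0.64 ± 0.07 (adjusted p 1.5e-07). Among blood cell miRNAs 2 of 8 rose, miR-486a-5p and miR-486b-5p (log2 fold 0.46 ± 0.08 in both, adjusted p 1.2e-04 in both), which come from overlapping hairpins on opposite strands and cannot be told apart, while miR-142a-3p had 0.53 ± 0.38 (adjusted p 0.347, camera adjusted p 0.626). Among neuronal miRNAs 2 of 7 rose and 1 fell over all names, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p 0.785). miR-128-3p had a log2 fold of 0.41 ± 0.07 (adjusted p 2.5e-05), miR-129-5p 0.71 ± 0.18 (adjusted p 0.0035), miR-219a-5p -0.42 ± 0.12 (adjusted p 0.012, lost without si-NC 3 at 0.074) and miR-129-1-3p -0.85 ± 0.35 (adjusted p 0.072). The muscle, endothelial and liver and serum lists had 2 tested members each and no list test. miR-206-3p fell and miR-1a-3p had -0.40 ± 0.40 (adjusted p 0.507). miR-126a-3p had -0.17 ± 0.11 (adjusted p 0.273) and miR-126a-5p -0.19 ± 0.14 (adjusted p 0.356). miR-192-5p fell and miR-194-5p had -0.11 ± 0.06 (adjusted p 0.204). The term for the 3 sets of libraries that differ in invertebrate names leaves the log2 fold to si-METTL3 1 against si-NC 2 and si-NC 3 alone. In that fit the calls of miR-743b-3p, miR-29b-1-5p, let-7c-5p, miR-92a-3p, miR-222-5p, miR-34c-3p, miR-741-3p, miR-30b-3p, miR-143-3p, miR-192-5p, miR-877-3p, miR-219a-5p and miR-200b-3p did not hold, each with a larger SE. These include every call made without the term in the X-linked testis cluster and the miR-29 family. The log2 folds were then -0.51 for miR-877-3p, -0.43 for miR-219a-5p, -0.65 for miR-200b-3p, 0.58 for miR-34c-3p, -0.28 for miR-30b-3p and -0.13 for let-7c-5p. They were -0.35 for miR-222-5p, -0.28 for miR-741-3p, -0.15 for miR-143-3p, -0.09 for miR-192-5p and -0.07 for miR-92a-3p.

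The miR-23, miR-27 and miR-24 miRNAs come from the same polycistrons, on chromosome 8 and on chromosome 13, and moved in different directions. miR-27a-3p (log2 fold 0.31 ± 0.04, adjusted p 1.0e-06, edgeR) rose with miR-27b-3p. miR-24-3p fell with miR-23a-3p (-0.30 ± 0.05, adjusted p 3.5e-05) and miR-23b-3p (-0.19 ± 0.04, adjusted p 0.0018); the 3 miRNAs other than miR-24-3p and miR-27b-3p were named after their values were seen. The mouse names do not hold all reads of an arm. miR-23-z, whose 24 bases extend miR-23b-3p by 3 bases, amounted to 22.1% of miR-23b-3p in si-NC and 42.9% in si-METTL3, a change in the log2 ratio of 0.96 ± 0.07 (adjusted p 1.5e-04, limma). With the names of each arm summed, miR-23b-3p had a log2 fold of 0.063 (adjusted p 0.296, range over its 23 alternatives 5.3e-06 to 0.296), so its fall did not hold, while miR-23a-3p remained lower (-0.21, adjusted p 0.0015) and miR-27b-3p higher (0.35, adjusted p 5.2e-07).

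**Figure D4:**
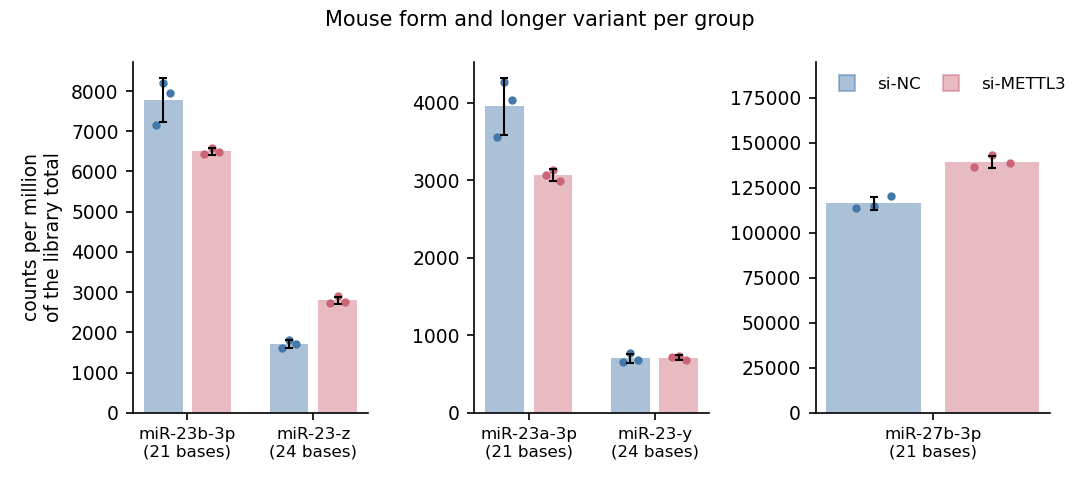
CPM of the library total (y axis, starting at 0 and scaled per panel) for the mouse form and the longer variant of miR-23b-3p (left), of miR-23a-3p (middle) and for miR-27b-3p (right), with bars for the mean of 3 libraries, bars of SD and 1 point per library, si-NC in blue and si-METTL3 in red. In the left panel the mouse form is lower and the longer variant higher in si-METTL3, where the variant reaches 42.9% of the mouse form against 22.1% in si-NC.

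The authors' deposited table of differently expressed miRNAs lists 50 names, 35 higher and 15 lower, which are the names with a p under 0.05 and an absolute log2 fold of at least 1 in their full table. Of these, 19 are mouse names, 27 carry names of other species, 16 of them with no match to a mouse hairpin, and 4 are predicted. The median total over the 6 libraries was 23.5 counts and 38 of the 50 had under 60 counts. The authors chose this list on the same libraries, so it is not independent evidence. Only 11 of the 50 passed the filter on low counts. Without that filter all 50 were tested and 19 passed, 11 of them names the filter had left out. Of these 11 only 2 are mouse names and 5 are invertebrate names. Among the 5, miR-8-z and miR-236-y, named after their values were seen, hold the same counts in every library. miR-122b-3p and miR-137-y, the latter likewise named, also matched no mouse transcript. All 11 that passed the filter had the same direction, and 7 passed the test (edgeR, Benjamini-Hochberg adjustment), named here after their values were seen except for the first 2. These were miR-5121 and miR-12135-z, then miR-375-3p (log2 fold -0.92 ± 0.25, adjusted p 0.0066), miR-1843b-3p (1.51 ± 0.40, adjusted p 0.0051), miR-769-x (5.70 ± 0.66, adjusted p 3.6e-07), miR-425-x (1.23 ± 0.37, adjusted p 0.014) and miR-128-z (1.12 ± 0.36, adjusted p 0.021). The call of miR-425-x was lost without si-NC 3 or si-METTL3 3 (0.102 and 0.090) and that of miR-128-z without si-NC 2, si-NC 3, si-METTL3 2 or si-METTL3 3 (0.067 to 0.102). With the term for the 3 sets of libraries the log2 fold comes from si-METTL3 1 against si-NC 2 and si-NC 3 alone. The calls of miR-12135-z (log2 fold 0.75 ± 0.29), miR-375-3p (-0.74 ± 0.36), miR-425-x (1.26 ± 0.53) and miR-128-z (1.14 ± 0.54) did not hold in that fit. Conversely, 175 of the 182 names past the threshold here were not on the authors' list. That list requires an absolute log2 fold of at least 1, which only 7 of the 182 reached here. The 175 therefore do not show a disagreement between the tests. Without a fold cut, the authors' own FDR was under 0.05 for 168 names.

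The mouse names with the largest folds on the authors' list rested on few counts. miR-122b-3p had 0 counts over si-NC and 16 over si-METTL3, at least 4.24-fold higher against a floor of 3 counts over the group, and miR-365-1-5p had 0 and 6, at least 1.59-fold higher. miR-1247-3p had 2 and 15 (ratio 5.96 in CPM, 95% exact interval 1.39 to 53.7), miR-1247-5p 5 and 33 (ratio 5.24, 2.03 to 17.2) and miR-344-5p 3 and 15 (ratio 3.97, 1.12 to 21.4). Both arms of miR-1247 lie on chromosome 12 in an exon of Dio3os. Among the falls, miR-7083-5p had 7 and 0 counts, at least 2.94-fold lower. miR-190b-3p had 11 and 1, miR-7654-5p 12 and 2, miR-1958 9 and 2, and miR-8106 15 and 4, with ratios of 0.0722 (0.00168 to 0.497), 0.132 (0.0144 to 0.595), 0.177 (0.0186 to 0.853) and 0.212 (0.0512 to 0.665). None of these 10 passed the filter on low counts, and without it miR-122b-3p (adjusted p 0.0043, edgeR) and miR-1247-5p (0.0066) passed the test. The intervals cover counting error only.

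No measure of composition could pass a test of 3 against 3 libraries, whose smallest exact p is 0.1. In 20 of the 31 measures, 10 higher and 10 lower in si-METTL3, the groups did not overlap (exact p 0.1), where chance gives 10%. The measures depend on each other, since most are shares of one total and lists share members, so the 20 are not separate results. The 10 most abundant names held 59.7% ± 0.354 of a library in si-METTL3, 1.21 percentage points more than in si-NC (exact two-sided permutation p 0.1, adjusted p 0.155 over 31 measures). The difference was 0.359 points for the 20 most abundant names and 0.691 for the 10 most abundant mouse names among mouse counts. The totals were 4018140 ± 30155 reads in si-NC and 5058010 ± 931864 in si-METTL3 (exact p 0.1), and 1055 ± 7.64 against 1093 ± 28.8 names were detected (exact p 0.1). Names of other species that match a mouse hairpin held 4.52% ± 0.107 in si-NC and 4.92% ± 0.0275 in si-METTL3 (exact p 0.1), and those that match none 0.157% ± 0.0130 and 0.175% ± 0.0203 (exact p 0.3). Among the latter were 16 names of invertebrate miRNAs, such as bantam and miR-750, 10 of them on the authors' list. Counted once per sequence (15 sequences), they summed to 54.2 ± 53 CPM of the library total in si-NC and 102 ± 30.6 in si-METTL3 (exact p 0.3), with 1.73 CPM in si-NC 1. Of the 4 invertebrate names past the filter on low counts, 0 passed in edgeR's quasi-likelihood test (adjusted p 0.237 to 0.977, 0 at an unadjusted p under 0.05), 0 in DESeq2 and limma, and 1 in edgeR's exact test. Without the filter 5 of the 16 passed.

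**Figure D5:**
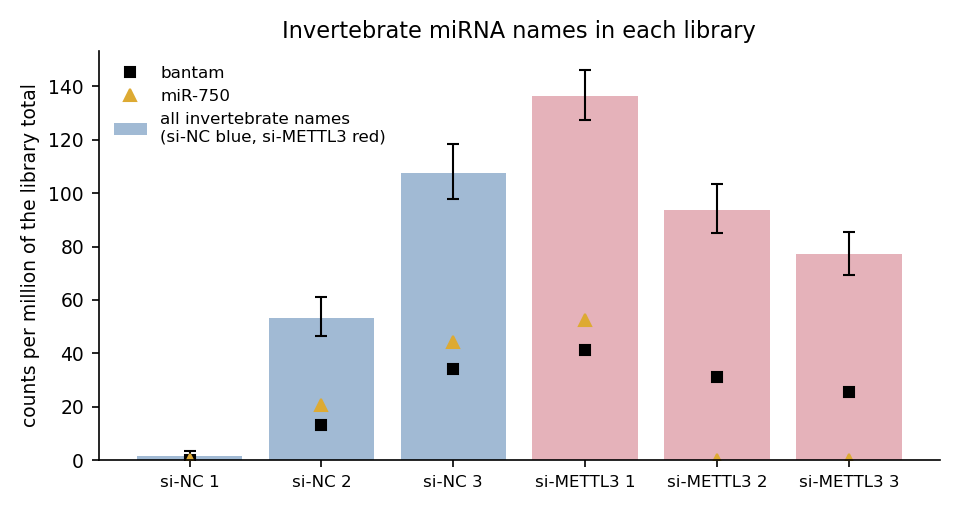
CPM of the library total (y axis) in each library, summed over 16 invertebrate miRNA names counted once per sequence (15 sequences). Bars (si-NC in blue, si-METTL3 in red) carry 95% exact binomial intervals that cover counting error only. Black squares show bantam and yellow triangles miR-750. si-NC 1 holds 1.73 CPM, the other libraries 53.3 to 136, and miR-750 is at 0 in si-NC 1, si-METTL3 2 and si-METTL3 3.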

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

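The tests of GC content on the whole set of changes, of library depth, of other splits, of the source of invertebrate names and of variants summed per arm were chosen only after the results were seen.

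Invertebrate miRNA names gave a signal outside the main measurement. They reached a mean of 102 CPM in si-METTL3, and si-NC 1 held 2.15% of the mean of the other si-NC libraries. Reads from another organism are a candidate explanation that stays open, since that value is the observation itself and no independent test of it was run. One single foreign source of constant makeup is argued against: over the 5 libraries that hold them, 9 names with at least 20 counts gave a chi-square over degrees of freedom of 15.9, against at most 6.38 in 10000 draws of mouse names of like counts. This rests mostly on miR-750, which had 581 counts in si-NC 2, si-NC 3 and si-METTL3 1 and 0 in si-METTL3 2 and si-METTL3 3, and without it the value was 3.56, with a share of 0.038 of draws as high. No biological explanation was tested.

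The many small changes between si-METTL3 and si-NC were weighed against processing. After a GC trend was removed 90.7% of the 182 names remained called with the same sign, and after thinning to one depth 92.3%, so neither accounts for the whole. The invertebrate names part the libraries into 3 sets, and contrasts that share no library, si-METTL3 1 against si-NC 2 and 3 and the mean of si-METTL3 2 and 3 against si-NC 1, correlated over 207 mouse names (r 0.87, rho 0.848, permutation p 1e-05, the smallest that 100000 permutations can give, adjusted p 4e-05 over 4 relations), which sets of libraries handled apart would not give. The 10 splits of the 6 libraries are too few for a share under 0.05, with 182 names in the real split, the only 1 of the 10 to reach that, and at most 1 in any other. The METTL3 siRNA stays open as an untested biological explanation, as do other differences between the transfections, since the labels print one sequence for both siRNAs and Mettl3 was not measured.

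The rise of miR-27b-3p beside the fall of miR-23b-3p within one polycistron was a gap of 0.52 ± 0.06 (SE, log2). With variants summed the gap was 0.29 ± 0.06, so reads split over names may account for part of it and not for the whole. The fall of miR-23b-3p itself ended under this sum, with a log2 fold from -0.19 to 0.063 (SE 0.04 in both), because reads of the longer variant that gained were added. A GC trend removed left the gap at 0.52, as both sequences have the same GC content and shift alike. Different stability or trimming of the 2 miRNAs after siRNA was not tested.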

How the results depend on the processing

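The alternatives with library sizes summed over the table, variants summed, mouse hairpins only, the GC trend, one depth and the 3 sets of libraries were chosen only after the data were seen. Of 182 names called, all kept their direction in each alternative that tested them, except 1 of 141 with variants summed, mmu-miR-23b-3p, which went from -0.19 to 0.063 (adjusted p 0.296) because reads of its longer variant were added. The count was 153 to 171 without 1 library, 156 with DESeq2, 165 with the exact test and 187 to 190 with limma. With a replicate block it was 176 (175 of the 182 kept). Deviations from the group mean correlated at -0.064, 0.023 and -0.239 over miRNAs between libraries of one number. These values show no positive relation by number. They cannot exclude a pairing, since the deviations of a group sum to 0 and the values constrain each other. With a term for the 3 sets of libraries 122 names passed, 82 higher and 40 lower, and 111 of the 182 remained; that term uses 2 of the 4 residual degrees of freedom.

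A requirement of an absolute log2 fold of at least 1 left 7 names, 6 of them higher and 1 lower. The fixed list tests passed 0 lists, and 0 to 3 without 1 library (3 without si-NC 1, 1 without si-NC 2, 1 without si-METTL3 1). They passed 1, the miR-322/miR-503 cluster, with total count only, with no filter on low counts, with mouse miRBase names only, with limma at each pseudocount, with the GC trend removed and with the most abundant arm of each hairpin. The cause was not tested. Of the 9 other splits of the 6 libraries 3 passed a list, at most 2 lists, and the real split passed 0. The cluster's adjusted p in camera was 0.0504 with the block. With the term for the sets its median log2 fold was 0.26. The overlap with the authors' deposited list was 7, became 9 at an unadjusted p under 0.05 and 11 with edgeR's exact test at an unadjusted p under 0.05. The composition measure, 1.21 points for the top 10, was 0.359 for the 20 most abundant names and 0.691 for mouse miRBase names only; the cause was not tested.

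For the 103 named miRNAs with a test, 2331 alternative values were computed. Of these 2177 kept direction and side of the threshold, 80 lost the call, 73 gained it and 1 reversed, and 22 of the 72 called lost the call with their direction kept in at least 1 alternative, beside mmu-miR-23b-3p, whose call ended with a turned sign. The calls of miR-743b-3p, miR-34b-3p, miR-877-3p, miR-200b-3p and miR-128-z were also lost with DESeq2's Wald test. The filter on low counts left out 39 of the authors' 50 names, of which 11 passed with no filter on low counts. Of these 11, 2 were mouse names and 5 were invertebrate names.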

Other observations

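The tests on 3′ variants and the neighbour test without Sfmbt2 members were chosen only after the results were seen, as were the names in this part. Some longer forms of miRNAs moved apart from their mouse form. The ratio of variant to mouse form rose in 7 arms and fell in 2 of 79 (limma, two-sided, Benjamini-Hochberg adjustment). After miR-23-z the largest gains in this ratio were those of miR-342-y (log2 ratio 0.80, 4.47% to 7.72% of miR-342-3p) and miR-331-y (0.69, 17.3% to 28.0% of miR-331-3p). Next came miR-125-y (0.66, 4.99% to 7.89% of miR-125b-2-3p) and miR-224-x (0.48, 53.7% to 74.9% of miR-224-5p). miR-125-y itself did not rise (log2 fold -0.12 ± 0.12, adjusted p 0.501, edgeR), and its ratio rose with the fall of miR-125b-2-3p. miR-30-y fell from 14.8% to 10.0% of miR-30a-3p. That longer 3′ variants gain in general could not be told from an even split (two-sided sign test, exact p 0.18).

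If primary transcripts set the level, arms of one hairpin and neighbouring hairpins might move together. Arms of 85 hairpins correlated weakly (r 0.26, rho 0.287, permutation p 0.0145, adjusted p 0.0145 over 4 relations), short of the r fixed for a shared cause, and 35 hairpins had arms of opposite sign. Of 21 with both arms called, 6 had arms of opposite direction (miR-125b-1, miR-23b, miR-24-1, miR-26b, miR-27a and miR-30b), where the fall of miR-23b-3p did not hold with variants summed. Each miRNA entered with 1 hairpin only, so miR-125b-2, which shares miR-125b-5p and also had called arms of opposite direction (0.26 and -0.78), is not among them. Dominant arms of hairpins within 10 kb correlated over 49 pairs (r 0.44, rho 0.36, permutation p 0.0015, adjusted p 0.0019) and over 42 pairs without Sfmbt2 members (r 0.41, permutation p 0.0073), which may point to shared transcripts. Of these 42 pairs only 26 had log2 folds of equal sign. The correlations are across miRNAs that share hairpins or pairs, so they are not over independent replicates.

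If METTL3 acted through its motif in hairpins, names whose hairpin holds GGAC might be lower. The 42 with GGAC had a mean log2 fold of 0.05 and the 151 without it 0.0076, a difference of 0.046 (95% interval -0.08 to 0.17, two-sided permutation p 0.405). That interval leaves little room for a lower mean of the 42 as a set. It cannot exclude small falls in part of them, which a mean dilutes. It also covers only motifs inside annotated hairpins, and flanking sequence was not analysed here. Log2 fold and GC content of the sequence correlated over 274 names (r 0.20, rho 0.197, permutation p 8.0e-04, adjusted p 0.0016).

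miR-769-x, which matched no mouse transcript, had 1 count in si-NC and 84 in si-METTL3, a ratio of 66.7 in CPM (95% exact interval 11.7 to 2667).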
